A study of Oryza sativa with 4 samples.

How the data were processed

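Total RNA of whole rice seedlings (Oryza sativa, japonica cultivar Nipponbare, 14 days old, grown in soil pots in a greenhouse) was labelled with Cy3 and hybridised to a custom 1-colour Agilent array. The labels give 2 groups of 2 arrays, wild type and transgenic line 40, which overexpresses the class I homeodomain-leucine zipper gene LOC_Os02g43330, and the series design states biological replicates. All 4 arrays lay on the same slide and share 1 scan time, so neither separates the groups. Each array carried 55078 non-control probes for 52795 loci of the MSU rice annotation, and 2282 loci had more than 1 probe.

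Each scanner file holds spot intensity on a linear scale, per the file headers from Agilent Feature Extraction version 10.7.1.1. The processed signal is the spot intensity after that software's background subtraction and detrending, per the file headers, with no normalization between arrays. The value table of the whole series held the same intensity as the authors deposited it in the scanner files: the ratio of both was 1 for each of the 62976 spots of every array, and its column medians were 61.8, 74.4, 57.1 and 63.3. It was matched to the spots by their feature number. Its scale is therefore linear and its columns are not centred, and as these are 1-colour signals they carry no direction. Flags of the same software, deposited with the spots, gave the probes that were well above background and the spots with uneven pixels. The array design in the headers rests on an older rice assembly (IRGSP5) than the gene table used for names (ASM3414082v1), so no coordinates are given.

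The main values were log2 of the processed signal minus the array's 75th percentile of it over non-control probes, a log2 scale derived here from the deposited intensity. The 75th percentile lay at signals of 367 and 488 on the wild type arrays and 404 and 431 on the overexpressor arrays. Control spots (1319) were left out, spots flagged as uneven were dropped, which removed 32 probes, and the spots of 459 probes printed more than once were averaged. A locus was tested if its probe was well above background on both arrays of at least 1 group. It was represented by the probe with the highest mean. This left 36902 loci. Among 1977 loci with more than 1 tested probe, 22 had a probe past the threshold: all tested probes were past it for 13, only part of them including the reported one for 5, another probe than the reported one for 4, and no locus had probes past it in opposite directions.

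Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3, version 1.17.8 of data.table) and Benjamini-Hochberg adjustment over all tested loci, with a threshold of 0.05. Values are given as mean ± SD over 2 arrays, and the SE of a difference is limma's moderated one. With 2 arrays per group the number of arrays limits the precision. For a locus not well above background on both arrays of 1 group, the fold is a lower bound ("at least"): the mean of the bright group against the mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. That lowest signal lay between 9.97 and 10.9 on the 4 arrays.

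Before the data were examined, 16 gene lists with 234 loci were written down by hand, together with the comparison, the threshold, the alternatives and the rule for named genes. These lists covered class I homeodomain-leucine zipper genes, abscisic acid and dehydration, gibberellin, diterpenoid phytoalexins, pathogenesis-related proteins, jasmonate, clock and flowering, photosynthesis, root markers, nitrogen uptake, phosphate starvation, iron homeostasis, ethylene and low oxygen, cell wall and lignin, cell division and meristem, and heat shock. Probes existed for 229 of these loci and 200 were tested. Lists with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the lists. An estimated correlation and fry, which tests whether a list's genes move on balance one way, served as alternatives. Both rest on the spread within groups of very few arrays, so they can miss a real shift of a list. Each list's median was also set against 10000 random lists matched on mean signal.

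The rule named the overexpressed gene, the 12 loci with the largest rise and the 12 with the largest fall among those past the threshold, well above background on all 4 arrays and with no overlap between groups, up to 5 loci each way measured in 1 group only, and the 4 members of each list with the smallest adjusted p. The files pair probes with MSU locus identifiers and give no symbols or descriptions, and the gene table used here holds no MSU identifiers. Symbols therefore come from the hand-written lists. They were checked against the gene table by chromosome and order along it: 155 symbols passed, 2 were out of order, 5 lay on another chromosome and 72 had no entry, so that their names rest on the lists alone. The 7 that failed are not named by symbol. Of loci outside the lists, at most 2 that rose and 2 that fell are printed, and the rest are summarised. Other members named were chosen after their values were seen, and the values of 1 member that the rule names are not reported here.

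The steps were tested on simulated arrays with the real mean signals of the 36902 loci. Their variances were drawn at random from limma's fitted prior, with independent noise for each locus. Of 50 loci per size, limma recovered 0% at a log2 change of 1, 62% at 2, 90% at 4 and 100% at 6, with 7 unchanged loci called and no wrong sign. With no change simulated, 0 loci and 0 lists were called. With the photosynthesis list raised by a log2 of 0.7, camera called 1 list, the raised one. The simulated loci varied independently, so these list results cannot show how camera behaves where the genes of a list vary together.

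Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter on dim probes, a filter on all 4 arrays, other rules for several probes of a locus, the replicate number as a block, eBayes with a trend and robust prior, the series value table, and each array left out in turn. Normexp was planned on the mean signal. It was run on the median signal and the local background median, which the scanner files used here hold. Cyclic loess was added after seeing the data. Families defined by keywords in gene descriptions, a promoter motif test and the removal of neighbouring loci with the same description were planned and not run, since they need descriptions or a genome that were not used here.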

Results

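Transcript levels were measured in whole 14-day-old Nipponbare seedlings of the wild type (n = 2 arrays) and of transgenic line 40 (n = 2 arrays). Line 40 overexpresses the class I homeodomain-leucine zipper gene LOC_Os02g43330, and the question was which genes differ in it. As this was the only transgenic line, the differences are those of line 40 and cannot be assigned to the overexpressed gene itself. Between 39709 and 39821 of 55078 probes were well above background on the wild type arrays, and between 37498 and 37908 on the overexpressor arrays. Across tested loci, Pearson's r was 0.983 between the wild type arrays, 0.991 between the overexpressor arrays and 0.963 to 0.977 between groups; loci are not independent replicates.

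LOC_Os02g43330, named HOX24 in the lists, was far more abundant in the overexpressor. Its normalized log2 signal was 2.05 ± 0.09 (SD, n = 2) in the wild type and 9.25 ± 0.14 (SD, n = 2) in line 40, a difference of 7.20 (SE 0.16), or 147-fold (limma adjusted p = 0.00105). Processed signals were 1449 and 2116 on the wild type arrays and 229120 and 280180 on the overexpressor arrays. The locus had 1 probe, and its rise was the largest among the 34057 loci measured on all 4 arrays.

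In total, 766 loci changed, 343 of them higher and 423 lower in the overexpressor. Among the 34057 loci measured on all 4 arrays, 280 rose and 137 fell, 277 and 136 of them at least 2-fold. The 12 largest rises in that set, HOX24 first, ranged from 15.1-fold to 147-fold, and the 12 largest falls from 4.28-fold to 29.1-fold lower. Behind HOX24, LOC_Os07g32710 rose 136-fold, with a log2 difference of 7.09 (SE 0.16, adjusted p = 0.00105), and LOC_Os06g17000 fell most, with a log2 difference of -4.86 (SE 0.16, adjusted p = 0.00333), or -3.20 after normexp. HOX24 was the only one of these 24 loci in the lists.

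A further 195 loci were well above background on both overexpressor arrays and on no wild type array, and 1188 showed the opposite. LOC_Os03g02470 had the largest bound, at least 682-fold higher in line 40 (adjusted p = 0.00422), and LOC_Os01g22230 was at least 56.4-fold lower (adjusted p = 0.00105). These bounds hold for the processed signal: after normexp, with its offset of 50, the fitted log2 differences were 6.69 and -3.50, smaller in size than the bounds. Of the 195 higher and 1188 lower loci, 53 and 265 passed the test. The bound reached 2-fold for 63 of the higher and 305 of the lower loci, and 35 and 102 of these also passed. Most of the lower calls were dim: 270 of 423, or 63.8%, fell in the dimmest 10% of tested loci, where the median log2 difference was -0.50, against 0.13 in the brightest 10%. The count moved to 399 without wild type replicate 1 (74 higher, 325 lower) and to 1802 without wild type replicate 2 (303 higher, 1499 lower). Without the filter on dim probes 23 loci passed, HOX24 among them, and none of the 15 other list members reported below as past the threshold did (adjusted p 0.0582 to 0.0979). Quantile normalization gave 251 higher and 155 lower loci, and median scaling, which moved the median of all loci by 0.15 from -0.06 to 0.08, gave 1486 and 1250.

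**Figure D1:**
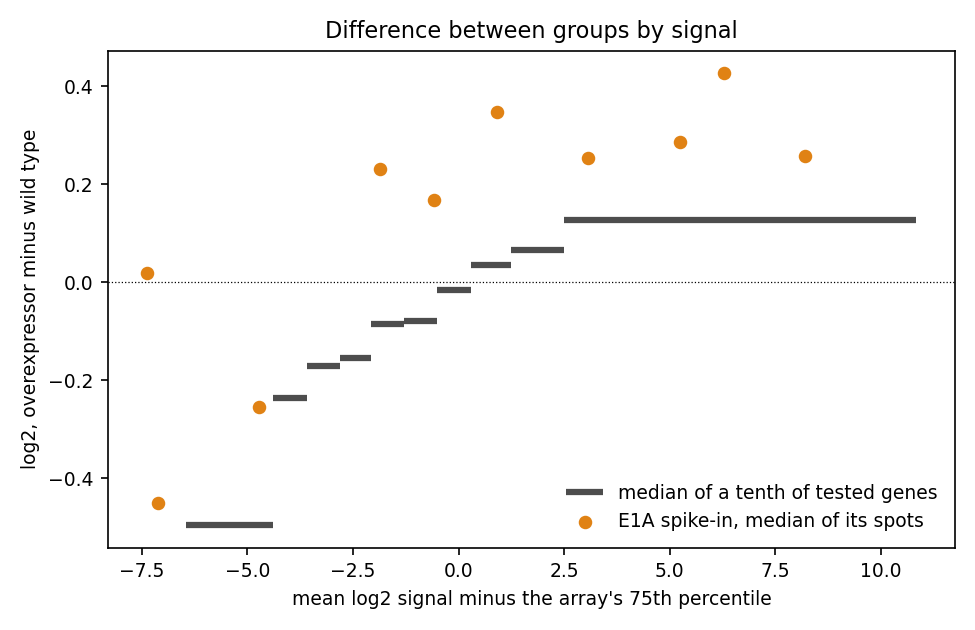
Difference between the groups by signal. The horizontal axis is the mean log2 signal minus the array's 75th percentile, the vertical axis the log2 difference of overexpressor minus wild type; bars are medians of consecutive 10% shares of the 36902 tested loci over their signal range, and points are the E1A spike-in controls, each the median of 35 spots averaged over 2 arrays per group. These medians run from -0.50 in the dimmest to 0.13 in the brightest.

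Genes of diterpenoid phytoalexin synthesis, which makes antimicrobial compounds, were higher in the overexpressor as a group by camera (list median 0.94, adjusted p = 8.46e-07). The list was not called with an estimated correlation (adjusted p = 0.782) or with fry (adjusted p = 0.0656). With so few arrays both tests can miss a real shift. KSL4 (LOC_Os04g10060), a diterpene synthase of the momilactone pathway, rose 10.1-fold, from -4.38 ± 0.28 to -1.04 ± 0.19 (SD, n = 2; log2 difference 3.34, SE 0.21, adjusted p = 0.00897). KSL10 (LOC_Os12g30824), another diterpene synthase, rose 7.16-fold (2.84, SE 0.18, adjusted p = 0.00988). The cytochrome P450 gene CYP99A2 (LOC_Os04g10160) rose by 1.55 (SE 0.16) and the copalyl diphosphate synthase gene CPS2 (LOC_Os02g36210) by 1.49 (SE 0.16). Of 11 tested members, 4 rose and none fell over all loci, 7 rose when adjusted over the list alone, and 10 lay above 0. CPS4 (1.34, SE 0.20, adjusted p = 0.0513) did not pass. The list's median was 0.49 after normexp and 0.57 without overexpressor replicate 2. After normexp the differences of KSL4 and KSL10 were 1.66 and 2.25. Both passed with each array left out but not without the filter (adjusted p = 0.0582 and 0.0587), whereas CYP99A2 and CPS2 passed only without wild type replicate 2, with adjusted p up to 0.0865 and 0.101 without another array, and CPS2 missed the threshold after normexp (0.49, adjusted p = 0.144).

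Among pathogenesis-related genes, PR1b (LOC_Os01g28450), a defence marker gene of the PR1 family, rose 6.26-fold, from -0.57 ± 0.15 to 2.07 ± 0.07 (SD, n = 2; 2.65, SE 0.16, adjusted p = 0.00868), and it passed with each array left out but not without the filter (adjusted p = 0.0582). GNS5 (LOC_Os01g71340), a beta-glucanase gene, rose 2.04-fold (adjusted p = 0.0475), a call that was lost with any of the 4 arrays left out (adjusted p 0.0658 to 0.190). CHT1 (0.82, SE 0.14, adjusted p = 0.0647) and PR5 (1.43, SE 0.28, adjusted p = 0.0778) missed the threshold. Over all loci, 2 of 14 tested members rose and none fell; adjusted over the list alone, 7 rose and 1 fell. The member that fell was JIOsPR10, at -0.47. WRKY45 and NH1, regulators of salicylic acid signalling, lay at -0.09 and -0.28 (adjusted p = 0.745 and 0.401). The list's median was 0.59 (camera adjusted p = 0.00669, and adjusted p = 0.863 with an estimated correlation), or 0.39 without wild type replicate 1.

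In the iron list, 4 of 12 tested members rose. The nicotianamine synthase genes NAS2 (LOC_Os03g19420) and NAS1 (LOC_Os03g19427) rose 3.12-fold and 2.57-fold, to 0.95 ± 0.01 and 4.95 ± 0.0043 (SD, n = 2) from -0.69 ± 0.01 and 3.59 ± 0.06 (adjusted p = 0.0181 and 0.0277). YSL15 (LOC_Os02g43410), a transporter of iron chelated by phytosiderophore, rose 3.03-fold (1.60, SE 0.22, adjusted p = 0.0452). One more member, whose symbol failed the check, rose 2.43-fold. None of the 12 fell over all loci, 5 rose when adjusted over the list alone, and 11 lay above 0. The ferritin genes FER1 and FER2, which store iron, lay at 0.29 and 0.39 (adjusted p = 0.647 and 0.526). Their differences were -0.20 and -0.09 without overexpressor replicate 1, and 0.79 and 0.88 without overexpressor replicate 2. The list's median was 0.62 (camera adjusted p = 2.03e-05, and adjusted p = 0.635 with an estimated correlation). It was 0.52 without wild type replicate 1 and 0.93 without overexpressor replicate 1. All 4 calls were lost without wild type replicate 1 or either overexpressor array (adjusted p up to 0.129), and YSL15 also missed the threshold after normexp (0.57), quantile normalization and cyclic loess (adjusted p up to 0.0955).

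Photosynthesis genes of the nucleus were higher as a group by camera (list median 0.74, adjusted p = 1.50e-11). This list too was not called with an estimated correlation (adjusted p = 0.782) or with fry (adjusted p = 0.0656), tests limited by the few arrays. Of 22 tested members, 21 lay above 0; 3 rose and none fell over all loci, and 17 rose when adjusted over the list alone. The 3 were a Rubisco small subunit gene (RBCS, LOC_Os12g17600; 2.71-fold, from 5.96 ± 0.09 to 7.39 ± 0.08, SD, n = 2; adjusted p = 0.0276), a light-harvesting protein gene of photosystem II (LHCB, LOC_Os07g37240; 2.60-fold, adjusted p = 0.0357) and PSBO (LOC_Os01g31690), a subunit of the oxygen-evolving complex (2.17-fold, adjusted p = 0.0409). PSBQ of the same complex missed the threshold (0.98, SE 0.15, adjusted p = 0.0533). Rubisco activase RCA, at 0.09 (SE 0.16), and the light-harvesting genes CAB1R and CAB2R, at -0.09 (SE 0.15) and 0.18 (SE 0.16), lay within 2 SE of 0. RBCS passed only without wild type replicate 2, and LHCB and PSBO were lost with any array left out (adjusted p 0.0522 to 0.157); quantile normalization put all 3 above the threshold (adjusted p up to 0.0863). Root markers, measured in the same seedlings, had a median of -0.18 over 15 tested members (mean -0.05, camera direction upward, adjusted p = 0.842), with none past the threshold. That median was -0.39 without overexpressor replicate 1 and 0.10 without overexpressor replicate 2. Adjusted over the list alone, 2 aquaporin genes lay higher (PIP2-5, 1.14, SE 0.18, and PIP2-3, 1.19, SE 0.22) and the ammonium transporter gene AMT1-2 lower (-1.36, SE 0.21). After normexp PIP2-5, PIP2-3 and AMT1-2 passed over all loci (limma adjusted p = 0.0136, 0.0193 and 0.0304). AMT1-2, AMT1-3, NRT2.1, NRT2.2 and NAR2.1 stand in both the root and the nitrogen list, and all lay below 0. Of the 15 root markers, 6 lay above 0.

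**Figure D2:**
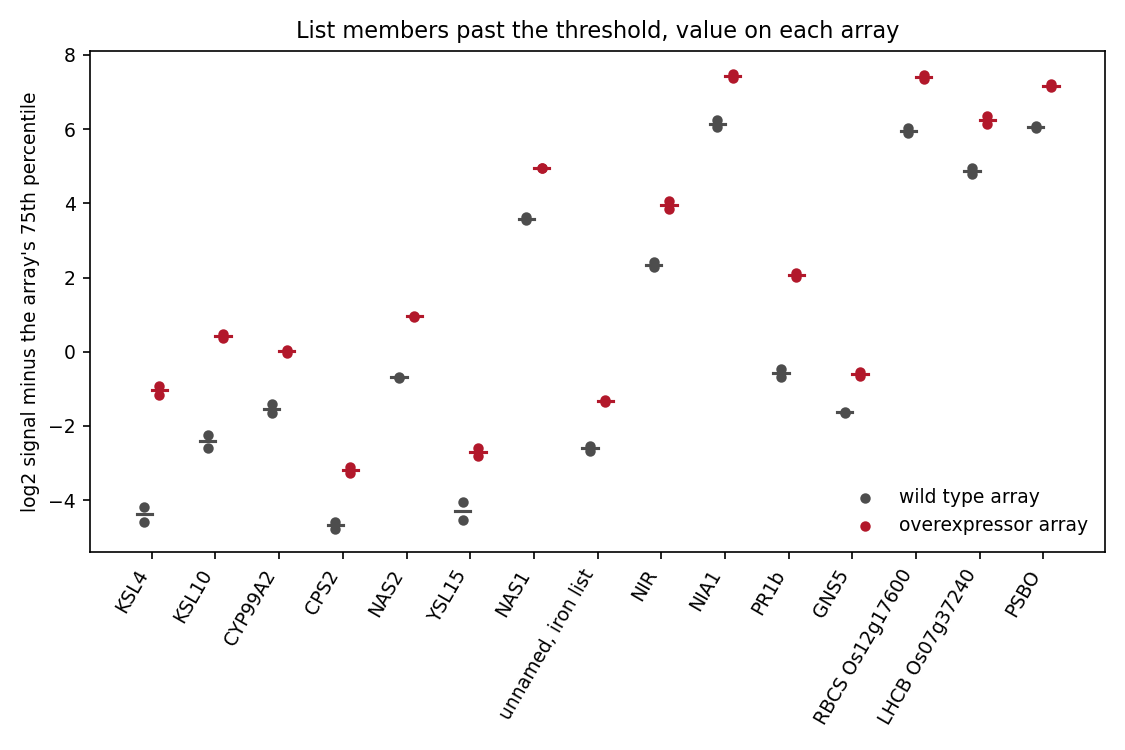
Members of the gene lists past the threshold, apart from HOX24. The vertical axis is log2 signal minus the array's 75th percentile; each point is 1 array and each bar the mean of 2 arrays, in grey for the wild type and red for the overexpressor. All 15 genes are higher in the overexpressor, with no overlap between groups, such as PR1b (mean -0.57 against 2.07) and NAS1 (3.59 against 4.95).

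In the nitrogen list the members that passed were the enzymes of nitrate reduction. Nitrite reductase NIR (LOC_Os01g25484) rose 3.05-fold (1.61, SE 0.16, adjusted p = 0.0240) and nitrate reductase NIA1 (LOC_Os08g36480) 2.45-fold (1.29, SE 0.15, adjusted p = 0.0356). The other 7 members lay below 0, among them the nitrate transporter gene NRT2.3 (-1.64, SE 0.29, adjusted p = 0.0667) and AMT1-2 (-1.36, SE 0.21, adjusted p = 0.0552), and none of these passed. After normexp NRT2.3 (-1.51, adjusted p = 0.0167) and AMT1-2 (-0.94, adjusted p = 0.0304) did pass. Adjusted over the list alone, 2 rose and 2 fell. The list's median was -0.33 (camera adjusted p = 0.842), or -0.81 without overexpressor replicate 1 and 0.032 without overexpressor replicate 2. The calls of NIR and NIA1 were lost without wild type replicate 1 or either overexpressor array. That of NIA1 was also lost after quantile normalization (adjusted p = 0.0833) and cyclic loess (adjusted p = 0.0520).

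No relative of HOX24 passed the test over all loci. Among 8 tested class I homeodomain-leucine zipper genes, only HOX24 itself rose. HOX4 lay at -0.72 (SE 0.14, adjusted p = 0.0783), HOX13 at -0.50 (SE 0.15, adjusted p = 0.133) and HOX6 at -0.41 (SE 0.15, adjusted p = 0.182), and adjusted over the list alone HOX24 rose and 2 members fell. The median was -0.28 and the mean, which HOX24 pulls up, 0.66 (camera adjusted p = 0.842, direction downward). Camera was run with HOX24 in the list, so its result does not test the relatives alone. The adjustment over the list alone also included HOX24, which eases the threshold for its relatives. HOX13 passed it only narrowly (limma p adjusted over the list 0.0484), so that count does not test the relatives alone either. The median was -0.17 without wild type replicate 2 and -0.13 with median scaling.

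For abscisic acid and dehydration, none of 25 tested members passed, over all loci or adjusted over the list alone. In the simulation limma recovered 0% of loci at a log2 change of 1, so changes of that size can be missed. Fewer loci were changed in the simulation than the 766 called in the data, which made its adjusted threshold stricter. In the data GNS5 passed at 1.03, so the 0% does not carry over exactly. The list's median of 0.13 missed the threshold (camera adjusted p = 0.0580). The list passed without wild type replicate 2 (0.16, adjusted p = 0.0273) and without overexpressor replicate 1 (0.21, adjusted p = 0.00322). ABA8OX3, an abscisic acid hydroxylase gene, lay at 0.65 (SE 0.15, adjusted p = 0.0951), the dehydration gene WSI18 at 1.42 (SE 0.33, adjusted p = 0.0984; 0.60 after normexp), and NAC10 at -0.65 (SE 0.16, adjusted p = 0.105). RAB16A, RAB16B, RAB16D, SALT and the DREB1A and DREB2A genes, among others, were not well above background on both arrays of either group and were not tested.

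Jasmonate genes had a median of 0.30 over 14 tested members (camera adjusted p = 0.0580), with none past the threshold over all loci and 3 higher when adjusted over the list alone. These were the repressor gene TIFY11a (1.11, SE 0.20), the oxophytodienoate reductase gene OPR1 (0.65, SE 0.16) and the lipoxygenase gene HI-LOX, not well above background on either wild type array and at least 1.96-fold higher in processed signal (adjusted p = 0.0801), though its log2 difference after normexp was 0.27 (adjusted p = 0.471), below that bound. The list passed without wild type replicate 2 (0.46, adjusted p = 0.0277) and without overexpressor replicate 2 (0.39, adjusted p = 0.0260). Cell division and meristem genes had a median of 0.45 over 9 members (camera adjusted p = 0.0615), none past the threshold on either count, with the cyclin gene CYCB2-1 at 0.51 (SE 0.14) and PCNA at 0.46 (SE 0.18). That list passed without wild type replicate 2 (0.47, adjusted p = 0.0302).

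No member of the clock and flowering list passed over all loci, and 1 of 15 was lower when adjusted over the list alone. GI lay at -0.80 (SE 0.21, adjusted p = 0.117), or -0.054 after normexp, and the list's median at -0.15 (camera adjusted p = 0.318); without wild type replicate 1 the list passed (-0.38, adjusted p = 0.0489). The 13 gibberellin genes had a median of 0.01 (camera adjusted p = 0.518). The kaurene oxidase gene KO2 lay at -1.08 (SE 0.18, adjusted p = 0.0582), or -0.53 after normexp (adjusted p = 0.130). KO2 was the 1 member lower when adjusted over the list alone. Among 10 ethylene and low-oxygen genes (median 0.03, camera adjusted p = 0.528), the ethylene-forming oxidase gene ACO1 lay at 1.04 (SE 0.16, adjusted p = 0.0555) and was the 1 member higher when adjusted over the list alone.

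Heat shock genes had a median of -0.40 over 6 members (camera adjusted p = 0.253), with the heat shock factor gene HSFA2A at -0.62 (SE 0.15). Without overexpressor replicate 1 this list passed (-0.57, adjusted p = 0.0298). The 15 cell wall and lignin genes had a median of -0.10 (camera adjusted p = 0.382) and passed only after cyclic loess (-0.29, adjusted p = 0.0381), and the 7 phosphate starvation genes had a median of 0.06, a mean of -0.06 and camera adjusted p = 0.842. No member of these 3 lists passed on either count. The sign of the medians of the ethylene, cell wall and phosphate lists turned between scalings, and those of the clock, gibberellin, ethylene, cell wall and phosphate lists turned when 1 array was left out.

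**Figure D3:**
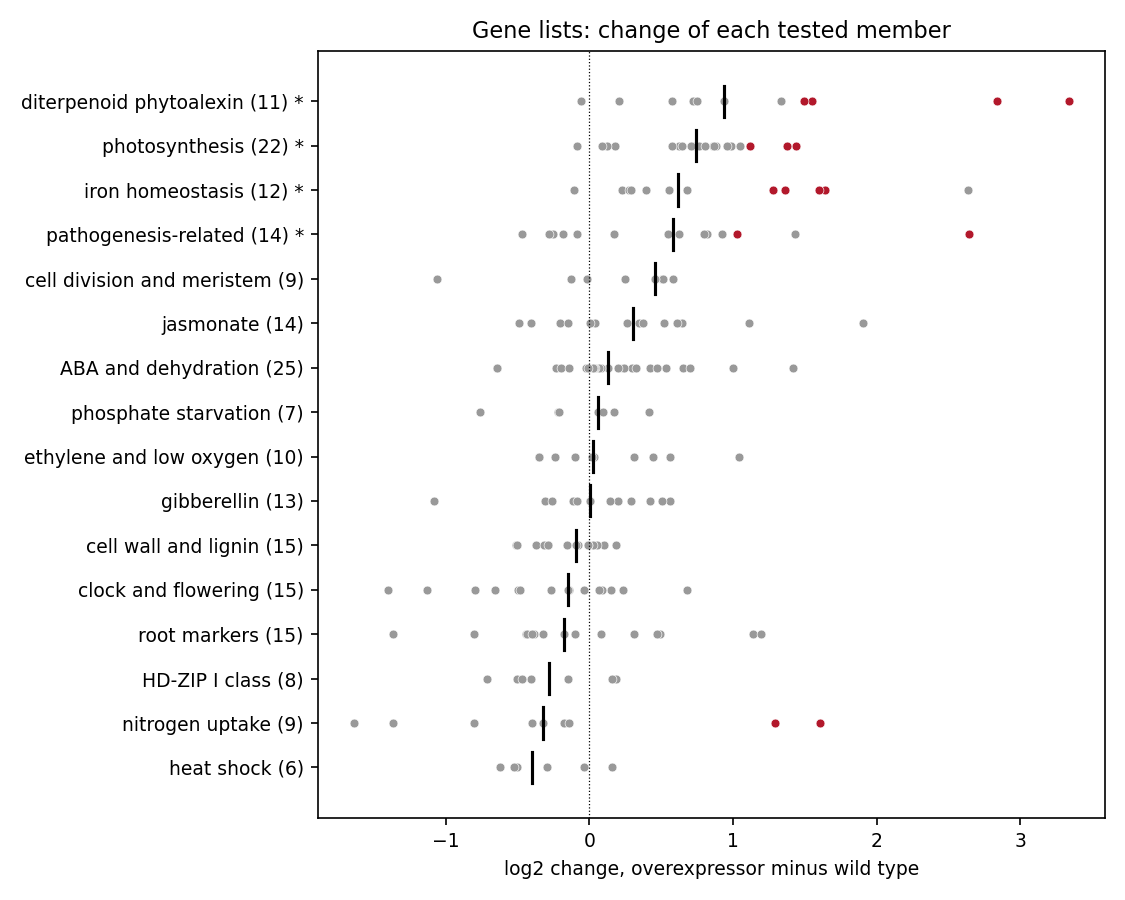
Log2 change of each tested list member, overexpressor minus wild type, on the horizontal axis, with 1 line per list and its number of tested members in parentheses. Points are genes, red if past the threshold over all loci and grey if not, black bars are medians of all tested members, asterisks mark the 4 lists called by camera, and HOX24 is left out of the points. The 4 marked medians lie between 0.59 and 0.94.

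Of the 16 lists, 4 were called higher and none lower by camera. None was called with an estimated correlation (lowest adjusted p 0.635) or by fry (lowest adjusted p 0.0656). Both of these tests rest on the spread within groups of very few arrays, so they can miss a real shift. Their result does not show that the 4 lists are unchanged, and the 4 calls rest on the preset correlation. Set against random lists matched on mean signal, as a description of these arrays, the medians of the 4 lists lay above the 95% range. So did those of the jasmonate and cell division lists, and those of the homeodomain-leucine zipper, nitrogen and heat shock lists lay below it, though camera called none of these 5.

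Around the endogenous HOX24 locus, 1 of the 10 nearest tested loci on each side, YSL15, had changed. Against 2.07% of the other 36881 tested loci, the difference of these 20 loci missed the threshold (Fisher's exact test, two-sided p = 0.342). The count was 3 without wild type replicate 2 and 0 without any other array.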

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

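Cyclic loess was chosen after seeing the data; every other alternative was planned. HOX24 stayed past the threshold in all 15 alternatives, between 7.10 and 7.30 with an array left out. No named gene past the threshold turned direction in any alternative. Of the 15 other list members past the threshold, 3 passed with each array left out, 8 under all 4 other scalings and background corrections, 10 with the replicate block and 0 without the filter on dim probes (adjusted p 0.0582 to 0.0979). The series value table holds the same signals and moves nothing, and the trend and robust prior does not enter camera. The keyword families, the promoter motif and the removal of like-described neighbours were not run.

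The count of 766 changed loci became 406 with quantile normalization, 2736 with median scaling, 23 without the filter, 504 with a filter on all 4 arrays and 3875 with the trend and robust prior, and 399 to 1802 with an array left out. Normexp gave 1099 loci (764 higher, 335 lower), of which 377 were shared with the 766, and cyclic loess 557 (303 higher, 254 lower; 516 shared). The replicate block gave 778, of which 575 were shared. The 1 changed neighbour of HOX24 became 0 with normexp, quantile normalization, no filter, the replicate block and cyclic loess, and 0 to 3 with an array left out. The 27 adjacent pairs became 70 with normexp, 13 with quantile normalization, 215 with median scaling, 1 without the filter, 390 with the trend and robust prior, and 7 to 117 with an array left out. The 1383 loci measured in 1 group only became 1512 to 2021 with an array left out.

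The 4 lists called became 7 without the filter, 5 to 7 with an array left out, and 0 with an estimated correlation or with fry, where the medians stayed as they were: 0.94 for phytoalexins, 0.59 for pathogenesis-related genes, 0.74 for photosynthesis and 0.62 for iron. With so few arrays an estimated correlation and fry can miss a real shift, so that 0 does not show unchanged lists. Abscisic acid passed with median scaling (0.28), without the filter (0.065) and with the replicate block (0.13), with a range of 0.081 to 0.21 over arrays left out. Jasmonate passed with median scaling (0.45), without the filter (0.26) and with the block (0.30), with a range of 0.14 to 0.46. Cell division passed without the filter (0.45; range 0.22 to 0.47), cell wall after cyclic loess (-0.29), and clock (range -0.38 to 0.016) and heat shock (range -0.57 to -0.28) with 1 array left out. An array left out leaves 1 in its group, assumed to vary like the other group; the cause of the other changes was not tested.

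Same-numbered arrays deviated from their group means with a correlation of -0.07 across loci, so the shared replicate numbers show no pairing, and the block is given here alone. Signal over background limits the dim loci: the dimmest 10% of loci hold 63.8% of the lower calls.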

Other observations

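Among the tests here, those on spike-ins, negative controls, the signal-matched and cyclic loess values of the photosynthesis list, root markers and the splits of the arrays were chosen after the result was seen, as was the check of the clock genes with 1 gene left out; the clock test itself and the test of the filter were written before their results were seen. The count of adjacent loci against shuffled calls was planned before the files were read, and the bound for reading it was written after.

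Changed loci lay next to each other more often than shuffled calls did. Of the 766 changed loci, 52 formed 27 adjacent pairs of tested loci that moved the same way, 17 pairs higher and 10 lower (7 pairs without wild type replicate 1 to 117 without wild type replicate 2, as the number of calls moved). The nicotianamine synthase genes NAS1 and NAS2 were such a pair, and so were GNS5 and LHCB (LOC_Os07g37240) each with a neighbour. Among the strongest changes, LOC_Os07g32710 (7.09) lay in a run with changed neighbours at fitted log2 differences of 3.32 and 5.80. LOC_Os01g22230 was paired with a neighbour at least 18.1-fold lower. The cause of these runs, seen in 1 transgenic line, was not tested. Shuffling the calls over tested loci 10000 times gave a mean of 8.04 pairs and at most 20 (p = 1e-04, the smallest these permutations can give), which argues against a chance order as the whole source of the 27 pairs. Tandem copies whose probes bind each other's transcripts and real co-regulation of neighbours both stay open, since no probe sequences were compared. The shuffles moved calls to loci of any signal, while most lower calls were dim. They therefore cannot tell whether neighbours alike in signal add to the 10 lower pairs.

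Dim genes were lower in the overexpressor arrays: the median difference ran from -0.50 in the dimmest 10% of loci to 0.13 in the brightest 10%. E1A spike-in RNA, added to each sample from outside, moved in part the same way. The 1 spike-in within the signal range of the dimmest 10% lay at -0.25 and the 7 brighter ones at a mean of 0.28. The difference was -0.54, with no overlap of arrays, against -0.46 for the genes. The brighter ones, at 0.17 to 0.43, did not rise steadily with signal as the genes did. Spike-ins dimmer than that range lay at 0.02 and -0.45. A signal-dependent scaling difference between the arrays may therefore contribute to the lower calls. Background subtracted too strongly on the overexpressor arrays is argued against by the negative controls, whose background-subtracted signal was 1.10 higher there, and selection by the filter as the whole cause by the unfiltered loci in the same signal range, whose median was -0.49 over 8961 loci, although it was -0.16 over the 1085 loci there that were above background on all 4 arrays. A change of weakly expressed genes in the plants stays open beside the scaling difference.

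The photosynthesis list's median of 0.74 lay at the 100th percentile of 10000 lists matched on signal (95% range 0.02 to 0.34), and it was 0.59 after cyclic loess, which argues against signal-dependent scaling as the whole cause, although camera with an estimated correlation did not call the list (adjusted p = 0.782). Relative to the 7 brighter spike-ins, which were 0.28 higher in the overexpressor, the median was 0.46. A smaller share of root in the seedlings cannot be told apart: the root markers had a median of -0.18 (-0.39 without overexpressor replicate 1, 0.10 without overexpressor replicate 2) and members that went both ways. That median is the value of AMT1-3, 1 of the uptake genes that this list shares with the nitrogen list, all of them below 0. The 6 root markers above 0 are not in the nitrogen list. Another hour of sampling also stays open, since the 6 tested clock genes had a median absolute difference of 0.20, at percentile 30.6 of matched lists, but between percentiles 15.2 and 60.9 with 1 gene left out. An effect of HOX24 stays open as the biological explanation that the design names, in 1 transgenic line.

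The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 766 loci and 9175 at an unadjusted p under 0.05, and it was the 1 split with as many. In the other splits limma called 0 loci, with 163 and 257 at an unadjusted p under 0.05. Each of those splits put 1 wild type and 1 overexpressor array on either side. The difference between the groups therefore widened the spread within each side and lowered these counts, so they do not show what chance alone would give.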
